A study of Homo sapiens with 32 samples.

How the data were processed

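CTCF, an insulator protein, and H3K9me3, a histone mark of silenced chromatin, were profiled by ChIP-seq in Jurkat cells, a human T cell leukaemia line. Per the labels, the cells carried KRAB-dCas9, a Cas9 without nuclease activity fused to a repressor domain, with a guide aimed at CTCF sites (sg4, [aag]sg4 or sg8) or with a Safe Harbor control guide. The labels describe the guides as 20 nt long or truncated and do not give their sequences. Of 32 samples in the series, 12 were used, matched by column name to 14 columns of 3 deposited tables. Each group held 2 libraries, named replicate 1 and replicate 2 in the labels. The labels do not say that replicates came from separate cultures, so p-values measured the spread between these libraries, which may be technical.

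The authors deposited raw counts per library, not normalized. Per the file headers, 2 tables held counts in 887980 windows of 500 bp at CTCF motif sites from JASPAR, with sg4, [aag]sg4 and Safe Harbor libraries in the first and sg8 and Safe Harbor libraries in the second. The remaining table held H3K9me3 counts of sg4 and Safe Harbor libraries in 617665 tiles of 5 kb. Per the submitters' processing notes, featureCounts, deepTools and the hg38 build were used. The aligner, peak filters and tool versions are not given in the sources used here. Coordinates are those of the deposited tables, on hg38.

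The 2 CTCF tables were not counted alike. Of all windows, 41.4% overlapped another window. There the Safe Harbor replicate 1 total in the sg4 table was 15.7% of that in the sg8 table, as if reads lying over several windows had been left out of the sg4 table and counted in each window in the sg8 table, a rule that was not tested. At the 393538 windows more than 400 bp from any other, the Safe Harbor replicate 1 counts of the tables were equal in 100% of windows. The column named Safe Harbor replicate 2 was equal in 14.9% of these windows and lower in the sg8 table in 46.5%, so the column of that name held different libraries in the 2 tables, of which 1 at most can be the labelled sample. All tests were made within a table.

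Total counts were 6360566 and 5238840 for Safe Harbor, 6630184 and 5489326 for sg4 and 6838190 and 5455245 for [aag]sg4 in the first CTCF table (replicates 1 and 2). In the sg8 table they were 10096874 and 12022962 for Safe Harbor and 5734320 and 6865413 for sg8. The H3K9me3 totals were 34472831 and 24576806 for Safe Harbor and 35584152 and 33937920 for sg4. Where a group had 0 counts in both libraries, a fold was given as a bound from a floor of 3 counts over the group, which covers counting error alone.

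Counts were tested with edgeR 4.0.16 under R 4.3.3 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest), with all libraries of a table in 1 fit and the guide as the only factor. This left 87534, 98733 and 566498 tested windows or tiles in the sg4 CTCF, sg8 CTCF and H3K9me3 tables. Benjamini-Hochberg adjustment ran over all tested windows, two-sided, with a threshold of 0.05. CPM values used TMM-scaled totals. The standard errors (SE) beside log2 changes were worked back from the test, as the absolute log2 change over the square root of its F statistic. They thus hold the same information as the p-values. With 2 libraries against 2, an exact permutation test of a single value cannot give a p below 0.333, so inference rested on the model across windows. Called windows within 5 kb were also counted as 1 region.

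Windows were named by the gene body they overlapped or else by the nearest gene body, protein-coding or lncRNA, in the RefSeq table of GRCh38.p14. In the gene list results they were mostly named by the list member nearby, even where another gene lay closer. That table gives gene bodies, and transcription start sites were not used here. Of its 59788 genes with a position, 783 on separate scaffolds were left out. For each comparison the text names the 12 largest falls and the 12 largest rises among called regions whose libraries did not overlap between groups and whose mean count reached 20 in the higher group. It also names up to 3 called regions per gene list and direction, and those lower in CTCF and touching a tile higher in H3K9me3. Some of these regions, and 1 of the gene lists, are not reported here.

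The gene lists reported were T cell receptor signalling, T-lineage transcription factors, CTCF and cohesin, H3K9 methylation machinery, clustered protocadherins, HOX clusters, imprinted genes, zinc finger genes of chromosome 19, ribosomal protein genes, cell cycle and apoptosis, and olfactory receptor genes. Positions were found for all members except that 387 of 390 olfactory receptor genes had one. A window belonged to a list when it lay within 10 kb of a member. The share of called windows in a list was compared with that in all other windows by Fisher's exact test, adjusted over the 12 lists tested per comparison and direction. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

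H3K9me3 at CTCF windows was read from the tiles they touched. Medians were set against 10000 random sets of tiles that hold a tested CTCF window, matched on mean H3K9me3 count and not on CTCF signal. Overlap of CTCF calls between guides was set against simulated groups without any change tested against the same control libraries, and against independent lists. As few simulated windows passed the threshold, ranked lists as long as the observed ones were compared too, which was added after seeing the data.

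The procedure was tested on simulated counts with known changes, placed only at windows or tiles with a mean count of at least 20. Recovery at weaker windows was not tested, and no difference by replicate number was built in. For the sg4 CTCF table, 42% of 2-fold and 97% of 4-fold changes were recovered, with 10 false calls among 73423 windows. For the sg8 table these values were 70% and 96%, with 3 false calls among 86309 windows, and for H3K9me3 55% and 99%, with 9 false calls among 565791 tiles. When a trend rising steadily with abundance was built into 83751 simulated sg8 windows, TMM gave 8649 false calls and intensity-dependent (loess) offsets 3. With these offsets 89 of 100 changes of 4-fold were recovered. The sg8 medians in the data did not rise steadily, at 0.86, -0.17 and 0.12 in deciles 1, 7 and 10 of abundance. The simulation therefore does not test the offsets on a trend of that shape.

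Alternatives were DESeq2 1.42.0, its size factors in edgeR, library totals alone, loess offsets (limma 3.58.1), no filter on low counts, a mean count of at least 20, the replicate number as a block, fits of the compared groups alone, leaving out each library, an adjusted p under 0.01, glmTreat with a fold of 1.5, and joined windows. Added after seeing the data were windows with no other window within 400 bp, loess offsets with a mean count of at least 20, the sg8 libraries summed, and an adjustment over the tiles at CTCF windows alone. Tables were handled in Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

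Whole-cell extract, dCas9 and untransduced libraries were not analysed here, nor was H3K9me3 in sg8 cells, for which 2 columns matched no labelled sample and were not used. CTCF in sg8 and sg4 was not compared directly, since no table held both. Guide sequences were not matched to the windows, because no genome sequence was used here.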

Results

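CTCF binding was measured with guides sg4, [aag]sg4 and sg8 and with a Safe Harbor guide as control, and H3K9me3 with sg4 and the control, with 2 libraries per group throughout. Total counts per library ran from 5238840 to 6838190 in the table that held sg4, [aag]sg4 and control CTCF, from 5734320 to 12022962 in the table that held sg8 and control CTCF, and from 24576806 to 35584152 for H3K9me3. In the first of these tables the libraries split by replicate number. Replicate 1 libraries had 53.7% to 57.2% of their counts in the 32545 windows with a mean count of at least 20, and replicate 2 libraries 43.1% to 45.8%. Libraries of the same number but different guides differed by 0.98 to 1.08 in chi-square per degree of freedom, and libraries of the same guide by 2.14 to 2.44. Changes within each replicate number are therefore given beside the pooled ones for that table. Those within a number were taken from log2 of CPM with 0.5 added, which draws them towards 0. The pooled ones came from the edgeR fit, so the sizes of the 2 kinds are not directly comparable.

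The first comparison asked where CTCF changed in cells with the guide sg4. The deepest fall lay 6.6 kb from UGT3A2, a gene of the UDP-glycosyltransferase family, on chromosome 5 from 36073517 to 36074016. CTCF there went from 18.3 ± 1.15 CPM (SD, n = 2) in the control to 3.58 ± 0.0537 CPM in sg4 cells, a log2 change of -2.35 (SE 0.302, edgeR adjusted p = 3.24e-10). CTCF also fell at windows inside IMPG2, a proteoglycan gene of the retina (-2.25, SE 0.398), and SLCO6A1, of the organic anion transporter family (-2.01, SE 0.317). It fell at windows 5.7 kb from SLC4A8, a bicarbonate transporter gene (-1.95, SE 0.352), 29.4 kb from SELENOK, a selenoprotein gene (-2.11, SE 0.319), and 59.7 kb from ORC5, whose product belongs to the origin recognition complex (-1.90, SE 0.314).

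Among non-coding loci, CTCF fell near LINC01378 (-2.33), LINC02156 (-1.93), LOC107984530 (-2.18) and LOC105377295 (-1.93) and inside LOC105370802 (-2.08). In all, 96 windows in 94 regions were lower, with log2 changes from -2.35 to -0.83 and a median of -1.43, which left 37.1% of the control signal. Of these windows, 40.6% lay inside protein-coding genes, against 51.2% of 3000 random tested windows. The median was -1.28 between the replicate 1 libraries and -1.38 between the replicate 2 libraries, and all 96 were lower within both numbers. No window was higher (0 by edgeR and 0 by DESeq2), with 906 higher and 953 lower at an unadjusted p under 0.05. With the replicate number as a block in edgeR, 172 windows were called lower, all 96 among them, and 2 higher.

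Several settings called fewer windows lower in sg4. DESeq2 called 29 of the 96, and 17 passed a test against a fold of 1.5. With library totals alone the count was 43, and with no filter on low counts, in a fit of 734168 windows, it was 0. Without sg4 replicate 2 it was 14, without sg4 replicate 1 it was 38, and without Safe Harbor replicate 1 it was 20.

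**Figure D1:**
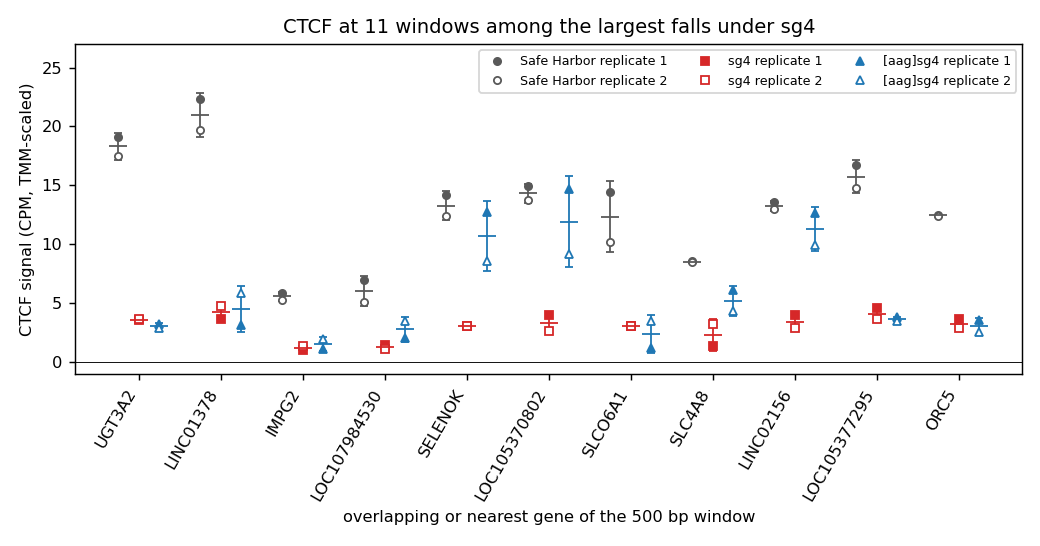
CTCF signal in CPM (TMM-scaled) at 11 windows among those with the largest fall under sg4, with a symbol for each of the 6 libraries and the mean ± SD (n = 2) of each guide as a dash and bar. At UGT3A2 and ORC5 both guides lay far below the control, and at SELENOK, LOC105370802 and LINC02156 the [aag]sg4 libraries lay above sg4.

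The second comparison asked the same of [aag]sg4. The window near UGT3A2 was again the deepest fall, with 24 and 15 counts in the [aag]sg4 libraries and 127 and 89 in the control libraries, a log2 change of -2.55 (SE 0.308, edgeR adjusted p = 9.87e-12). CTCF fell inside MID1, a ubiquitin ligase gene (-2.53, SE 0.360), SLCO6A1 (-2.49, SE 0.336), NHSL1 (-2.38, SE 0.298), IMPG2 (-1.94, SE 0.378) and SOX6, a transcription factor gene (-1.89, SE 0.319). It fell 5.5 kb from SFMBT2, a Polycomb group gene (-2.06, SE 0.288), and 59.7 kb from ORC5, where it was 3.99-fold lower. At non-coding loci the falls were -2.37 in LOC105374958, -2.28 near LINC01378, -2.10 near LOC105377295 and -1.91 at a window 63.5 kb from LOC105378400.

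In all, 39 windows in 39 regions were lower with [aag]sg4, with a median of -1.73 that left 30.2% of the control signal. The median was -1.83 between the replicate 1 and -1.36 between the replicate 2 libraries, and all 39 were lower within both numbers. The only window past the threshold in the other direction lay inside SNRPG, a gene of the small nuclear ribonucleoproteins, on chromosome 2 from 70293149 to 70293648. It held 1.39 ± 0.261 CPM in the control and 4.59 ± 0.419 in [aag]sg4 cells (n = 2; log2 change 1.74, SE 0.400, adjusted p = 0.0304). That call was lost with DESeq2, with loess offsets, with library totals and without any 1 library of either group. DESeq2 called 19 windows lower, 16 passed a test against a fold of 1.5, and 0 were called with no filter on low counts. The count was 19 without Safe Harbor replicate 1 or without [aag]sg4 replicate 1. With all libraries, 694 windows were lower and 863 higher at an unadjusted p under 0.05. With the replicate number as a block, 63 windows were called lower, all 39 among them, and 2 higher.

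The third comparison set [aag]sg4 against sg4 directly. At a window inside MTUS2, a gene for a microtubule-associated protein, on chromosome 13 from 29369061 to 29369560, CTCF was 14.3 ± 4.92 CPM (SD, n = 2) in the control, 14.9 ± 1.53 in [aag]sg4 cells and 3.91 ± 0.946 in sg4 cells. The log2 difference between the guides was 1.92 (SE 0.297, edgeR adjusted p = 5.18e-06). CTCF was likewise higher in [aag]sg4 than in sg4 inside LAMTOR3, a gene of nutrient signalling at the lysosome (1.79, SE 0.362), MAG, a myelin glycoprotein gene (1.67, SE 0.334), and NUDCD1 (1.62, SE 0.325). The same held near EBF3, a transcription factor gene (1.78, SE 0.373), and SELENOK (1.81, SE 0.324), and at the non-coding loci LINC01208 (1.89), LOC105378400 (1.86, 26.7 kb away), LOC105370802 (1.84), LOC105375470 (1.78), LINC02156 (1.71) and LOC105374600 (1.64).

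In all, 36 windows in 35 regions were higher in [aag]sg4 than in sg4, with log2 differences from 0.79 to 1.92, and medians of 1.31 and 1.32 between libraries of replicate numbers 1 and 2. All 36 were higher within both numbers. Of them, 34 were among the 96 windows lower in sg4, and at those 34 [aag]sg4 lay within -0.30 to 0.25 of the control on the log2 scale (median -0.02). The same sg4 libraries entered both tests, so low counts in them would favour both calls, and part of this overlap is built in. Choosing windows by a large difference between the guides also favours [aag]sg4 values near the control. No window was lower in [aag]sg4 than in sg4 by edgeR or DESeq2 (0 by each), with 685 lower and 913 higher at an unadjusted p under 0.05. With the replicate number as a block in edgeR, 95 windows were called higher, all 36 among them, and 1 lower. DESeq2 called 12 windows higher, and none of the 36 passed the test against a fold of 1.5 (0 by glmTreat). The count was 13 with library totals, 0 with no filter on low counts, 5 without [aag]sg4 replicate 1, 8 without sg4 replicate 1 and 0 without sg4 replicate 2.

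Windows lower with both guides numbered 29, among them those at UGT3A2, LINC01378, SLCO6A1, ORC5 and SFMBT2. Their median log2 change was -1.47 with sg4 and -1.79 with [aag]sg4, and [aag]sg4 lay below sg4 at 26 of the 29, none of which passed the test of that difference. Selection may add to this, since the [aag]sg4 list was shorter, 39 windows against 96, and its calls needed a smaller p. Independent lists of these lengths would share 0.0428 windows. In 10 simulations of unchanged groups against the same control libraries, the 96 and 39 most lowered windows by p shared 0 to 4, and too few windows passed the threshold there to share any (means of 0.3 and 0). The control libraries were too few to split, so part of the excess may come from sharing them. Fewer windows were shared in several settings, and more with the replicate number as a block. Without sg4 replicate 2 they numbered 5, without sg4 replicate 1 13, without Safe Harbor replicate 1 7 and without [aag]sg4 replicate 1 18, and DESeq2 gave 8, library totals 16, the test against a fold of 1.5 gave 7, and no filter on low counts gave 0. Another 33 of the 96 sg4 windows passed neither the [aag]sg4 test nor that of the difference between guides, with a median of -0.38 in [aag]sg4. At the 10 windows called in [aag]sg4 alone, among them ones inside ANO5, WDR72 and TMEM108, the medians were -1.29 with [aag]sg4 and -0.81 with sg4.

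**Figure D2:**
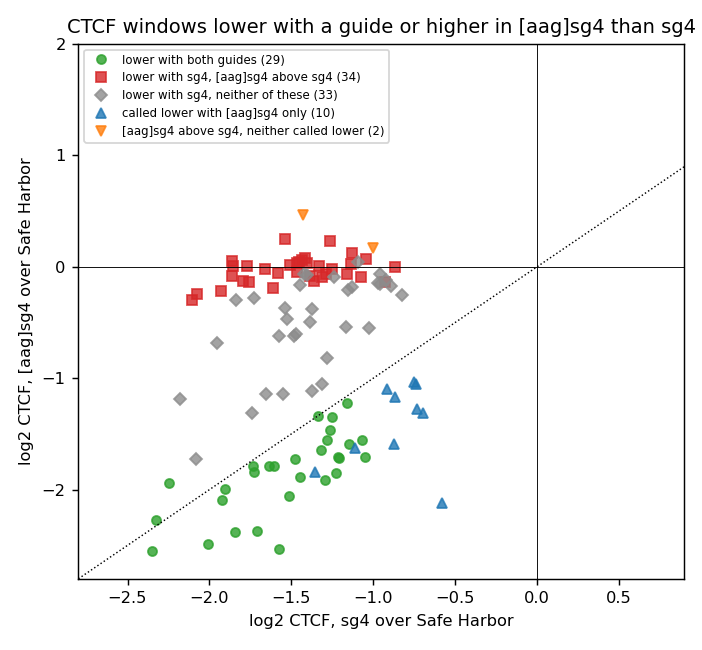
Log2 change of CTCF against the Safe Harbor control with sg4 (x axis) and [aag]sg4 (y axis) at windows called lower with either guide or higher in [aag]sg4 than in sg4, with equality as a dotted line. Of the 29 windows lower with both guides 26 lie below the line, and the 34 lower with sg4 and higher in [aag]sg4 lie near 0 on the y axis.

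The fourth comparison asked where CTCF changed with sg8. Its named falls included windows inside SAXO1 (-2.97, SE 0.319) and DELEC1 (-2.97, SE 0.399). Others lay in or near NMBR, the neuromedin B receptor gene (-2.81, SE 0.351), PWWP3B (-3.20, SE 0.716), LINC03063 (-3.21), LOC102723654 (-2.99), LOC124900864 (-2.89), LOC124901177 (-2.87), LOC105374524 (-2.84) and LINC01807 (-2.82). At SAXO1, on chromosome 9 from 19036550 to 19037049, CTCF went from 7.49 ± 0.596 to 0.960 ± 0.214 CPM (SD, n = 2; edgeR adjusted p = 6.60e-08). A window 76.5 kb from LOC124905258 had 41 counts in the control and 0 in sg8 and was at least 6.56-fold lower.

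In all, 1096 windows in 915 regions were lower with sg8 (median -1.22, which left 42.9% of the control signal) and 644 windows in 544 regions were higher (median 1.75). The falls lay mostly at windows of middle abundance (812 of 1096). Of the higher windows, 321 were in the lowest 2 deciles of abundance, with a median of 6 control and 20 sg8 counts, and 296 in the highest 2 deciles, with a median log2 change of 0.41. Named rises included 1.28 (SE 0.314) near NGRN, 0.82 (SE 0.175) and 0.80 (SE 0.156) near SULT2A1, a sulfotransferase gene, 0.69 (SE 0.181) inside PIK3R2, a regulatory subunit gene of phosphoinositide 3-kinase, 0.68 near WASHC1, 0.67 inside DNAJC11, 0.69 near LINC01800 and 0.64 inside LOC124906255. Another 4 lay 1094 to 1942 kb from their nearest genes, FAM230C (1.61), LINC02798 (1.19 and 1.13) and LOC105379476 (1.09).

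With offsets that depend on abundance, 1071 windows were lower, 857 of them among the 1096, and 82 were higher, 65 of them among the 644. The 12 largest falls and 12 largest rises under the naming rule all stayed past the threshold with these offsets. Higher windows were 37.0% of calls with TMM, 7.11% with these offsets and 11.5% with library totals, which moved the median of all windows by -0.25. DESeq2 called 518 lower and 14 higher. Without Safe Harbor replicate 1, 1822 windows were lower and 4105 higher, and without sg8 replicate 1 or replicate 2 the higher windows numbered 76 or 124. The sg8 libraries differed by no more than counting noise (chi-square 0.93 per degree of freedom) and, as their group had no other pair to set beside them, were kept as 2 samples. Summed to 1 sample, they gave 1137 lower and 253 higher windows.

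**Figure D3:**
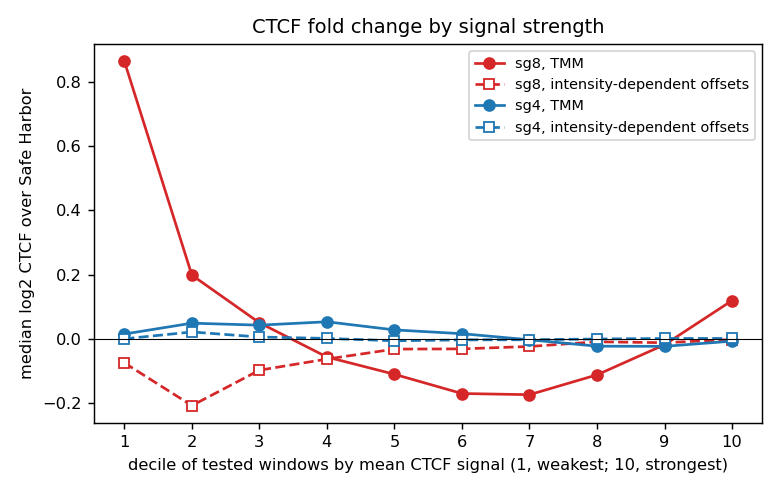
Median log2 change of CTCF against the Safe Harbor control (y axis) in each decile of the tested windows by mean signal (x axis), for sg8 and sg4, with TMM (filled circles, solid lines) and with intensity-dependent offsets (open squares, dashed lines). The sg8 median with TMM was 0.86 in the weakest decile and 0.12 in the strongest, and the sg4 medians stayed near 0.

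Among the gene lists, sg8 windows near imprinted genes were lower more often than other windows. Of their 92 windows, 7 were lower, against 1.11% of all tested windows (ratio 6.89, Fisher's exact test, adjusted p = 0.000944, range 0.000458 to 1 over the alternatives), and 10 adjusted over the list alone. Of the 7 windows, 6 overlapped or lay close together between 5.4 and 7.0 kb from CDKN1C, a cell cycle inhibitor gene. Their log2 changes ran from -1.97 to -0.77, the deepest at chromosome 11 from 2892759 to 2893258. The other lay 0.7 kb from MAGEL2 (-0.56, SE 0.117). With called windows within 5 kb counted once, 2 regions remained and the ratio was 2.48 (adjusted p = 1).

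In the other lists the share of sg8 windows called did not pass the test. The next smallest p was that of T cell receptor signalling, where 3 of 91 windows were higher (adjusted p = 0.264, and 3 adjusted over the list alone). These were a window inside PTPRC, a phosphatase gene of T cells (2.03, SE 0.461), and 2 overlapping windows 1.9 and 1.8 kb from CD5, a T cell surface protein gene (0.41, SE 0.0944, and 0.37, SE 0.101). The CD5 windows lay closer to VPS37C. With loess offsets the PTPRC call held (1.86, edgeR adjusted p = 0.0270). The only lower window of that list lay 1.9 kb from PLCG1, a phospholipase gene (-1.14, SE 0.133). Of 162 windows near T-lineage transcription factors, 2 were lower, both near LMO1, a T cell leukaemia oncogene (-1.86, SE 0.208, and -2.24, SE 0.310). Of 106 windows near CTCF and cohesin genes, 2 were lower, inside PDS5B, a cohesin regulator gene (-1.46, SE 0.150), and near CTCFL, a paralogue of CTCF (-1.28), and 4 adjusted over the list alone.

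Among 352 windows near zinc finger genes of chromosome 19, 3 were lower, of which 2 overlapping windows lay inside ZNF536 (-2.13 and -1.97), and 1 was higher. Ribosomal protein genes had 1 lower window of 266, near RPS27L (-1.73, SE 0.442), and 0 adjusted over the list alone. Cell cycle and apoptosis genes had 1 of 89, near CCND2, a cyclin gene (-1.59, SE 0.415). Olfactory receptor genes had 2 lower windows of 200, near OR6B3 (-1.06, SE 0.153) and inside OR56A1 (-0.63, SE 0.152), and 1 higher. The HOX clusters had 1 higher window of 60, inside EVX2 and 7.2 kb from HOXD13 (0.39, SE 0.106), and 4 adjusted over the list alone, and the clustered protocadherins 1 higher window of 64. With loess offsets the calls at CTCFL (-1.13, adjusted p = 0.0551), CCND2 (-1.52, adjusted p = 0.0741) and OR56A1 (-0.54, adjusted p = 0.0628) were lost with like estimates, and those at CD5 (0.17 and 0.20) and EVX2 (0.27) with lower ones. The scaling of the fit without a filter on low counts, which moved all tested sg8 windows by a median of -0.60, made the values at CD5 and EVX2 negative. In the H3K9 methylation machinery, 0 of 57 windows were called by edgeR or DESeq2, with 1 lower and 3 higher at an unadjusted p under 0.05.

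Few windows were lower with both sg4 and sg8. Of 96 sg4 and 719 sg8 lower windows tested in both tables, 2 were shared, inside STAU2, an RNA-binding protein gene, and inside LOC105375951, where independent lists would share 1.22. The 2 tables share a control library, and part of any overlap may come from it. At the sg8-lower windows the median change was -0.03 with sg4 and -0.03 with [aag]sg4, and at the sg4-lower windows it was -0.12 with sg8. In the sg4 and [aag]sg4 comparisons no list held a called window, by edgeR or DESeq2 (0 by each). Of all tested windows, 0.110% were called lower with sg4, 0.0446% lower with [aag]sg4 and 0.0411% higher between the guides. At such shares few or none would lie in the lists by chance, so these zeros say little about them. At an unadjusted p under 0.05, 7 of the 1252 windows in any list were lower and 20 higher with sg4, 7 and 14 with [aag]sg4, and 7 and 8 between the guides.

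The fifth comparison asked where H3K9me3 changed with sg4. It rose at tiles 9.8 kb from ZNNT1 on chromosome 8 (1.20, SE 0.211), inside LOC107984530 on chromosome 12 (1.10, SE 0.204), inside GDE1 on chromosome 16 (1.08, SE 0.203), 3.5 kb from SFMBT2 on chromosome 10 (1.07, SE 0.202) and nearest to LINC01720 on chromosome 1 (1.14, SE 0.213). At the tile near SFMBT2, from 7415001 to 7420000, it went from 1.37 ± 0.0269 to 2.90 ± 0.508 CPM (SD, n = 2; edgeR adjusted p = 0.0212). The tile also holds a window where CTCF fell (-1.52, SE 0.272), as does the tile at LOC107984530 (-2.18, SE 0.387). H3K9me3 fell inside COMMD5 (-1.12, SE 0.211) and near LOC105379397 (-1.04, SE 0.203). These 5 higher and 2 lower tiles were the only ones past the threshold, DESeq2 called 0, and 15053 tiles were higher and 15981 lower at an unadjusted p under 0.05. Without Safe Harbor replicate 1 the counts were 67 higher and 625 lower, and without Safe Harbor replicate 2 or sg4 replicate 1 they were 0 and 0. Without sg4 replicate 2, 1 tile was higher and 0 lower.

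H3K9me3 was raised at the windows that lost CTCF with sg4. The 102 tiles touching the 96 windows had 1.87 ± 0.0504 CPM in the control and 2.56 ± 0.0904 CPM in sg4 cells (SD, n = 2), with a median log2 change of 0.46 (1.38-fold), and 98 of the 102 were above 0. None of 10000 random sets of tiles matched on H3K9me3 abundance reached that median, and the highest was 0.0768. Of the 102, 51 were higher and 0 lower adjusted over the list alone (63 and 0 at an unadjusted p under 0.05), and 2 were among the 5 called over all tiles (Fisher's exact test, p = 3.21e-07). The change between mean CPM values was 0.47 for replicate numbers 1 and 0.45 for replicate numbers 2. With DESeq2, 4 tiles were higher over the list alone and 0 over all tiles, and the tiles over the list alone numbered 26 without H3K9me3 sg4 replicate 1. Fewer CTCF windows, and so fewer tiles, entered without CTCF libraries of sg4 replicate 1 (24 tiles), sg4 replicate 2 (11) or Safe Harbor replicate 1 (11), and the median without any 1 library was 0.45 to 0.57. The call of 2 tiles over all tiles went to 0 without any 1 of the H3K9me3 libraries except Safe Harbor replicate 1, where it was 4.

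**Figure D4:**
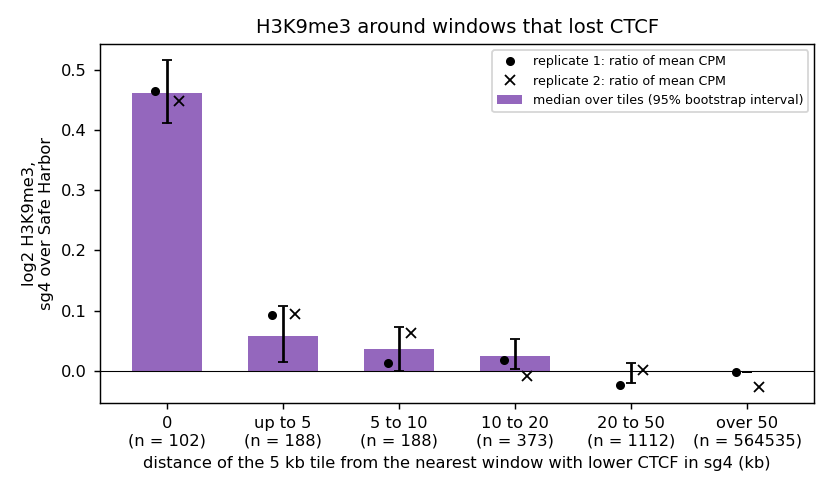
Median log2 change of H3K9me3 in sg4 cells against the control (bars, with 95% bootstrap intervals) by distance of the 5 kb tile from the nearest window with lower CTCF, with the ratio of mean CPM for each replicate number (circles and crosses). The median was 0.46 in tiles touching these windows and 0.06 in tiles up to 5 kb away.

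The rise was narrow. In tiles that touched no such window but lay up to 5 kb from one, the median was 0.06 (95% bootstrap interval 0.02 to 0.11, 188 tiles). From 5 to 10 kb it was 0.04, from 10 to 20 kb 0.02, and beyond 20 kb 0.00. At the 34 windows where [aag]sg4 lay above sg4, which include those at SELENOK, LOC105370802 and LINC02156, the median in sg4 cells was 0.42 (37 tiles, 17 higher adjusted over the list alone). At the 29 windows lower with both guides, which include UGT3A2 and ORC5, it was 0.48 (30 tiles). At windows lower with sg8, H3K9me3 in sg4 cells had a median of 0.02 (1010 tiles), and 259 of 10000 random sets were as high.

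No tile near a gene list was called in H3K9me3, by edgeR or DESeq2 (0 by each), with 103 of 6626 tiles higher and 452 lower at an unadjusted p under 0.05. Only 5 higher and 2 lower tiles were called among all 566498, so the absence of calls in the lists says little about them. Adjusted over the list alone, 1 tile was lower for CTCF and cohesin and 1 higher for ribosomal protein genes. The list medians were -0.26 for zinc finger genes of chromosome 19, -0.24 for clustered protocadherins, -0.09 for imprinted genes and between -0.03 and 0.00 for the other lists. Leaving out 1 library gave -0.41 to -0.12 for the zinc finger genes, -0.37 to -0.09 for the protocadherins and -0.18 to -0.01 for the imprinted genes.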

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

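The tests of matched windows, of H3K9me3 at the 34 windows, of the share of sg8 calls kept with other offsets, of random sets of tiles and of DNA copies were chosen after the results they address had been seen. The difference between [aag]sg4 and sg4 was tested directly, and 36 CTCF windows differed between these guides, all of them higher in [aag]sg4. At MTUS2, SELENOK and LINC02156, CTCF stayed near the control with [aag]sg4 and fell with sg4. A difference in ChIP enrichment between the 2 sets of libraries would move windows of like strength, and 690 windows matched on control signal that no comparison called had a median log2 difference of 0.0018 (25th to 75th percentile -0.10 to 0.09), against at least 0.79 at each of the 36. Chance low counts in the sg4 CTCF libraries would leave H3K9me3, measured in other libraries, as it was. At 34 of these windows its median was 0.42, above all 10000 random sets (highest 0.16). These values argue against chance alone for the sg4 falls at the 34 windows as a set. They cannot show that [aag]sg4 differs from sg4 there, because H3K9me3 was not measured in [aag]sg4 cells. A preference of [aag]sg4 for fewer of the sg4 sites is a candidate explanation that the design names, which was not tested against sequence, and the number of such sites stays open, since none of the 36 calls held without sg4 replicate 2 (0 windows), although all 36 were higher between the replicate 1 libraries (median 1.31).

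The 644 CTCF windows higher with sg8 sat at the weak and the strong end of abundance. An enrichment difference between the sg8 and control libraries that depends on abundance may account for many of them. With intensity-dependent offsets 10.1% of these calls were kept, and their median log2 change went from 1.75 (25th to 75th percentile 0.42 to 2.59) to 0.60 (0.23 to 1.07). The 321 higher windows at the weak end had medians of 6 control and 20 sg8 counts. The filter on low counts could keep such windows on sg8 counts alone. That selection was not told apart from an enrichment difference. In the 2 weakest deciles the offsets left medians of -0.07 and -0.21, so they may lower estimates there too far. The calls ended because the offsets lowered the estimates, to 1.02 at the weak end and to 0.22 at the strong end. Of the 27 higher windows of middle abundance 21 were kept, among them those near NGRN and inside PIK3R2, so the trend does not account for these. As fitted by these offsets, the same trend does not account for the falls as a set. Of these 78.2% were kept, with medians of -1.22 before and -1.11 after.

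H3K9me3 was higher where sg4 lowered CTCF. A property that all tiles with a tested CTCF window share does not account for it. The highest median among random sets of such tiles was 0.0768, below the 25th percentile of 0.33 at the 102 tiles. Of the 96 windows, 39, 38 and 7 lay in deciles 8, 9 and 10 of CTCF signal. The random sets were not matched on that signal, so they cannot test a property of strong CTCF windows alone. Loss of DNA copies of these loci in sg4 cells would give fewer reads with either antibody, and the median H3K9me3 change was 0.46. Deposition of H3K9me3 by the KRAB repressor at sites bound by sg4 is a hypothesis that these values are consistent with, found and tested on the same data. Guide sequences, dCas9 binding and whole-cell extract were not used here, so it stays open how many of the 96 windows were bound.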

How the results depend on the processing

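The tests on windows with no other window within 400 bp, with loess offsets joined to a mean count of at least 20, with the sg8 libraries summed, and with tiles adjusted over the list alone were chosen after the results were seen. So were DESeq2 and loess offsets for the guide overlap, H3K9me3 at CTCF windows and gene lists, library totals for the first 2 of these, and no filter, glmTreat and the compared groups alone for the overlap. The direction of change at named windows held under each alternative run except at 3 sg8 windows, where a scaling moved all windows alike, and the median H3K9me3 change at windows that lost CTCF stayed between 0.45 and 0.57 when any library was left out. Counts of called windows moved far more. Except where stated, the cause was not tested.

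With DESeq2, windows lower with sg4 went from 96 to 29, with [aag]sg4 from 39 to 19 lower and from 1 to 0 higher, between the guides from 36 to 12 higher, and with sg8 to 518 lower and 14 higher. DESeq2 called 0 higher and 0 lower H3K9me3 tiles, 8 windows shared by sg4 and [aag]sg4, 0 tiles at CTCF windows and 4 over that list alone, and 0 gene lists, with a ratio of 4.16 for imprinted genes. Against a fold of 1.5 (glmTreat), the counts were 17 lower with sg4, 16 lower and 0 higher with [aag]sg4, 0 between the guides, 401 lower and 20 higher with sg8, 0 and 0 H3K9me3 tiles, and 7 shared windows; this test asks for a larger change by construction.

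Without a filter on low counts, 0 windows were called lower with sg4 (22217 at an unadjusted p under 0.05), 0 lower and 0 higher with [aag]sg4, 0 between the guides, 0 shared, 10 higher with sg8, and 4 lower H3K9me3 tiles. The unfiltered fit covered 734168 windows of the sg4 table, and the trended dispersion at the 96 windows rose from 0.0180 to 0.0847. Its scaling moved all tested sg8 windows alike, by a median of -0.60 (5th to 95th percentile -0.61 to -0.58), which took the CD5 windows from 0.41 to -0.18 and from 0.37 to -0.23, and the EVX2 window from 0.39 to -0.20.

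With library totals alone, 43 windows were lower with sg4, 0 higher with [aag]sg4, 13 higher between the guides, 3164 lower and 412 higher with sg8, and 1 H3K9me3 tile lower, with 16 shared windows and 28 tiles over the list alone. Of the 6 H3K9me3 calls 83.3% were then higher, against 71.4% with TMM. Loess offsets gave 0 higher with [aag]sg4, 82 higher with sg8, 1 lower H3K9me3 tile and 0 called tiles at CTCF windows, and with a mean count of at least 20 as well 146 higher with sg8. A mean count of at least 20 alone gave 0 higher with [aag]sg4 and 2 gene lists past the threshold, the second being higher sg8 windows at HOX clusters. Fitting the compared groups alone gave 0 higher with [aag]sg4.

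Windows without a neighbour within 400 bp gave fewer calls because fewer were tested, with 25 lower with [aag]sg4, 23 higher between the guides, 468 lower and 229 higher with sg8, 19 shared, 1 called tile and 33 over the list alone. The summed sg8 libraries gave 253 higher windows. At an adjusted p under 0.01 there were 0 higher with [aag]sg4, 18 between the guides, 109 higher with sg8, 0 and 0 H3K9me3 tiles, 0 tiles at CTCF windows, 23 over the list alone and 0 gene lists (ratio 5.76). With called windows within 5 kb counted once, 0 lists passed (ratio 2.48).

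The replicate numbers were not taken as pairs in the main fits, since each comparison has 2 and the labels give no shared day or culture. The libraries of the sg4 table did split by number. Its unblocked fit took that split as spread within a guide, so its counts of calls may be too low. Deviations of same-numbered libraries from their group means correlated at 0.34 to 0.39 in the sg4 table, at 0.05 in the sg8 table and at -0.03 in H3K9me3. With the replicate block, 172 windows were lower with sg4, all 96 among them, and 2 higher, 63 lower and 2 higher with [aag]sg4, 1 lower and 95 higher between the guides, 4 H3K9me3 tiles lower, and 54 shared.

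Leaving out 1 library, with the lone library taken to vary like the others, gave 14 to 76 lower and 0 to 1 higher with sg4, 19 to 32 lower and 0 higher with [aag]sg4, 0 lower and 0 to 33 higher between the guides, 744 to 1822 lower and 76 to 4105 higher with sg8, and 0 to 625 lower and 0 to 67 higher H3K9me3 tiles. It gave 5 to 27 shared windows, 0 to 4 called tiles at CTCF windows and 11 to 41 over that list alone. Simulated 2-fold changes at windows or tiles with a mean count of at least 20 were recovered in 42% of sg4, 70% of sg8 and 55% of H3K9me3 cases. Counts of calls therefore leave out part of such changes, and recovery at weaker windows was not tested. Whole-cell extract offsets, sequence matches of the guides and the comparisons named as not analysed here were not run.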

Other observations

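The tests in this part, except that of the difference between the guides, were chosen after the data were seen. Windows that missed the CTCF threshold with sg4 also had raised H3K9me3. At 45 windows with less CTCF at an unadjusted p under 0.001 that were not called, the 51 tiles had a median H3K9me3 log2 change of 0.39 (95% bootstrap interval 0.31 to 0.54), and 44 of the 51 were above 0. The highest median of 10000 random sets of as many tiles was 0.13. The 8 tiles at windows with more CTCF at such a p had a median of 0.18 (0.07 to 0.22), which 301 of the random sets of their size reached. At an unadjusted p from 0.001 to 0.01 the medians were 0.14 (0.07 to 0.20, 157 tiles) for less CTCF and 0.00 (-0.03 to 0.07, 133 tiles) for more. As a hypothesis, some of the windows just short of the threshold may have been lowered by sg4, so that 96 would undercount them.

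The 10 windows called lower with [aag]sg4 alone include windows inside ANO5, WDR72 and TMEM108 and one 46.4 kb from IFNG-AS1. The H3K9me3 median of their 11 tiles in sg4 cells was 0.39, above all 10000 random sets (highest 0.27). Several of these windows also had less CTCF with sg4 at an unadjusted p under 0.001. Examples are the window inside TMEM108 (-1.11, edgeR adjusted p = 0.0971) and that near LOC105377897 (-1.36, edgeR adjusted p = 0.0517). They are thus also among the uncalled sg4 windows described above. The sets share tiles, so this median is not separate evidence from theirs. None of the 10 passed the test of the difference between the guides (0 by edgeR).

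Windows that lost more CTCF were not clearly those that gained more H3K9me3. Across the 96 windows, which are not independent replicates, Spearman's rho between the changes was -0.20 (permutation p = 0.0554) and Pearson's r was -0.24 (permutation p = 0.0201), so that the measures fell on either side of the threshold and the relation cannot be told apart from chance by rho.

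H3K9me3 at zinc finger genes of chromosome 19 had a median log2 change of -0.26 over 2143 tiles in sg4 cells, and at clustered protocadherins -0.24 over 133 tiles, with no tile called. The mean CPM of the zinc finger tiles was 2.89 and 3.56 in the control libraries and 2.78 and 2.47 in the sg4 libraries. Without Safe Harbor replicate 1 the medians were -0.41 and -0.37, without Safe Harbor replicate 2 -0.12 and -0.09, without sg4 replicate 1 -0.35 and -0.30, without sg4 replicate 2 -0.19 and -0.18, and with intensity-dependent offsets -0.09 and -0.07. By mean CPM, the zinc finger and the other tiles had medians of -0.09 and -0.03 under 1, -0.06 and 0.02 from 1 to 2, -0.24 and 0.00 from 2 to 3, -0.33 and -0.21 from 3 to 4, and -0.33 and -0.27 above 4.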
